A study of Drosophila melanogaster with 30 samples.

How the data were processed

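RNA of adult virgin male Drosophila melanogaster from a laboratory stock founded by flies caught in the field was measured on 30 Affymetrix Drosophila Gene 1.0 arrays, 3 for each of 10 diet histories. The food of each generation during development was poor or rich, and flies were frozen directly, and the RNA was biotin-labelled, per the labels' protocols. The compositions of the foods, the rearing dates, the number of flies per sample and the array batches are not given in the sources used here. The groups were taken from the group label of each sample.

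The authors deposited 1 normalized expression value per probe set and array, made with GCRMA per the submitters' processing notes (a method that corrects background by probe sequence, normalizes between arrays and summarizes probes into probe sets). The version of GCRMA and the probe-set definition are not given in the sources used here. The deposited values were taken as log2 values, the usual scale of this method. Their base is not stated, and the values, which run from -0.56 to 10.78 with 2 decimals, do not settle it. If they were natural logarithms, every difference given here on the log2 scale would be 1.44 times larger, and no p-value of limma would move. Medians over probe sets ran from 0.82 to 0.94 across arrays. Normalization between arrays brings medians together, so they cannot show that the arrays were alike. The number of arrays, 3 per group, limits the precision.

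The table held 15309 probe sets. Through the platform annotation, 13441 had 1 gene symbol, 555 had several and 1313 had none. Of the 13441, the gene identifiers of 13064 were found in a table of current gene names, and 0 symbols had to be updated. These probe sets covered 13402 genes, 37 of them with several probe sets. A probe set with several symbols or none was tested and counted, but never named. In the table, 553 probe sets shared all 30 values with another one, so distinct value profiles are given where they alter a count. The closest pair of arrays differed by 0.179 on average over probe sets, so no 2 of the 30 arrays held the same values. No genome was used, and no coordinates are given.

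A model of 10 group means was fitted to all 30 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, no covariate and no filter on dim probe sets), so that all groups share 1 estimate of each probe set's spread. P-values were adjusted by the Benjamini-Hochberg method over the 15309 probe sets of each comparison, and a probe set with an adjusted p under 0.05 was called. The 14 contrasts were the effect of a fly's own diet in each of 5 pairs of groups and on average over them, the effect of the parents' diet in F1 flies raised rich, raised poor and on average, the effect of the grandparents' diet in F2 flies raised rich, raised poor and on average, and the interactions of own and ancestral diet in F1 and in F2. Each contrast was taken as poor minus rich, and each interaction as the own-diet effect under poor ancestry minus that under rich ancestry. F tests with 2 degrees of freedom asked whether the own-diet effect differed among generations in the line with rich-raised ancestors, and whether F0, F1 and F2 flies with only rich food in their history differed. The model was tested on simulated data with 200 changed probe sets among 15309. Of the changes of 0.50, 1.00 and 2.00 on the log2 scale it recovered 16.4, 88.1 and 100 percent for own diet in F0, 95.5, 97.0 and 98.5 percent for own diet on average, 70.1, 95.5 and 100 percent for parental diet on average, and 7.46, 52.2 and 97.0 percent for the F1 interaction. The simulated noise was independent between probe sets, and for averages the change was the same in every pair. Far fewer than 200 probe sets were called in the real ancestral and interaction contrasts, where the adjustment is stricter. Recovery may therefore be lower there than in the simulation.

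For 25 gene lists, 350 pairs of list and contrast were tested with limma's camera at a preset inter-gene correlation of 0.01, with 1 probe set per gene (the one with the highest mean), and adjusted over the 25 lists of a contrast. The lists were insulin and TOR signalling, gut digestion, lipid metabolism, carbohydrate metabolism, amino acid metabolism, immune effectors, Turandot and heat shock genes, detoxification, cytosolic ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, proteasome, accessory gland, testis, Y-linked genes, fat body and larval storage, female and ovary, muscle, eye and neuron, Malpighian tubule, odorant-binding and chemosensory genes, cuticle, chromatin and piRNA, circadian clock, and cell cycle and DNA replication. The tissue lists cover tissues that could differ in amount in whole males. Pairs of lists share at most 6 genes. Camera with the inter-gene correlation estimated for each list, and limma's fry, were run beside it. Members of a list past the threshold were counted from the adjustment over all probe sets and again adjusted over the list alone.

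Genes were named by a rule: for own diet on average, the 12 highest and 12 lowest differences among called probe sets with the same sign in all 5 pairs. For each pair they were the 5 highest and 5 lowest among called probe sets whose 3 arrays per group did not overlap, and for ancestral diet the 10 highest and 10 lowest by the same rule (for averages, same sign in both contrasts). For interactions and F tests they were the 10 smallest p-values among the calls. Where nothing passed, the 3 smallest p-values in each direction were named as not passing. Up to 4 members of each list with the smallest adjusted p were added, and Lsp2, tobi, Pepck1, bmm, InR and Yp1 are given whatever their values. The translation inhibitor Thor and the insulin-like peptide gene Ilp6, also on that list, have no singly named probe set and are not analysed here. List members beyond these were chosen after their values were seen. The comparisons, the 25 lists, this rule and the alternative settings were fixed before the data were examined.

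These settings were the replicate number as a block, quantile normalization, centring of each array on its median, leaving out the dimmest 40% of probe sets, eBayes with trend and robust, array quality weights, a fit to only the groups compared, an estimated inter-gene correlation, and leaving out each array in turn. Leaving out the 2 arrays with ovary transcripts, leaving out 1 pair of groups from the own-diet average, and leaving out replicates 1 and 3 of R-R (F1 flies with rich food in both generations) were added after the data were seen. For each comparison the real grouping was set beside all 10 splits of its 6 arrays, or beside 100 splits drawn at random, the real one included. For averages the random splits were drawn within each pair of groups. For interactions and F tests arrays were exchanged freely among all groups compared.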

Results

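Gene expression was measured in whole adult virgin males on 30 arrays, in 10 groups of 3 that differ in the food on which the flies and their ancestors developed. Groups are written here by the foods of successive generations, with R for rich and P for poor. F0 flies were raised rich (R) or poor (P). F1 flies of either parentage were raised rich or poor (R-R, R-P, P-R, P-P). F2 flies had rich-raised F1 parents and rich-raised or poor-raised grandparents (R-R-R, R-R-P, P-R-R, P-R-P). The labels do not say that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Array medians lay between 0.82 and 0.94, and each array correlated with the others of its group at a mean r of 0.951 to 0.988 across probe sets, which are not independent replicates.

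Ovary and yolk genes were strongly expressed on 2 of these arrays from males, replicate 2 of R-P and replicate 2 of P-R-R. The 35 measured genes of the female and ovary list averaged 2.84 and 2.85 there, against 0.33 to 0.47 on the 28 other arrays. Yp1, which encodes a yolk protein, read 5.24 and 6.57 there and 0.19 to 0.74 elsewhere. The testis list averaged 3.26 on both arrays and 3.43 to 3.76 on the others, and the accessory gland list 4.82 and 4.84 against 4.87 to 5.21. Cuticle genes stood apart on 2 other arrays, replicates 1 and 3 of R-R, where their list averaged 0.520 and 0.507 against 0.612 to 0.773 on the remaining 28, and Lsp2 read 4.20 and 3.53 there against 5.40 to 7.63. The lowest Lsp2 values of that range are those of replicate 2 of P-R-R (5.40) and replicate 2 of R-R (5.68), and the next was 6.04. The muscle list averaged 4.93 and 5.14 on replicates 1 and 3 of R-R and 5.04 to 5.68 on the same 28. All 4 arrays stayed in every comparison under their labels. Values without them stand beside many, but not all, of the results that they alter. Without replicates 1 and 3 of R-R this group has 1 array, assumed to vary like the other groups.

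**Figure D1:**
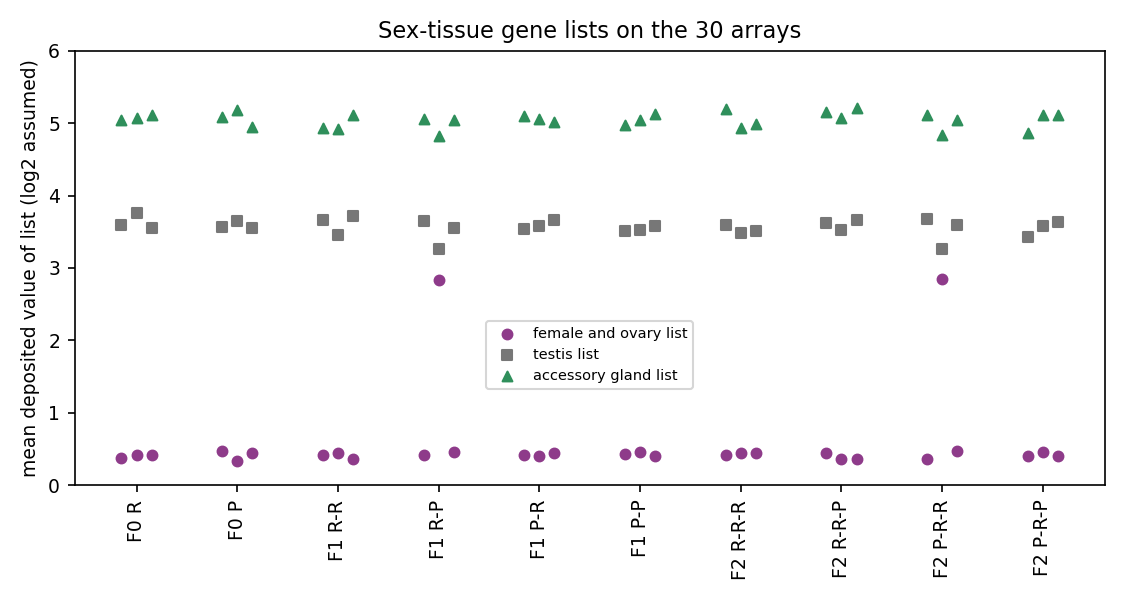
Mean deposited value (log2 assumed) of the female and ovary, testis and accessory gland gene lists on each of the 30 arrays, 1 point per array and list, by diet-history group. The ovary list reads 2.84 and 2.85 on replicate 2 of R-P and of P-R-R and at most 0.47 on the 28 other arrays.

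The first question was which genes follow the food a fly itself developed on, whatever its ancestors ate. Averaged over the 5 pairs of groups, single genes of xenobiotic metabolism were lower in poor-raised males and single cuticle genes higher. Differences are poor minus rich on the log2 scale with the standard error of the model, assuming base-2 logarithms (with natural logarithms each would be 1.44 times larger). CG16898 fell furthest, at -2.78 ± 0.12 (adjusted p = 1.52e-14), followed by the UDP-glycosyltransferase gene Ugt37A3 at -2.66 ± 0.35 (adjusted p = 2.74e-05). The glutathione S-transferase genes GstD2 and GstD5 fell by 1.93 ± 0.21 and 1.13 ± 0.18. The cytochrome P450 genes Cyp6d2 (-1.77 ± 0.13) and Cyp6a23 (-1.09 ± 0.12) and the aldehyde oxidase gene AOX1 (-1.58 ± 0.08, adjusted p = 1.15e-13) also fell. So did Arc1, which encodes a capsid-forming protein of neurons (-1.53 ± 0.13), mat (-1.40 ± 0.16), CG3285 (-1.27 ± 0.09), CG14125 (-1.27 ± 0.19) and CG3397 (-0.98 ± 0.14).

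Among the genes that rose, CG43114 led at 1.32 ± 0.15 (adjusted p = 2.39e-06), followed by Vajk2 at 1.16 ± 0.26 (adjusted p = 0.0146) and CG16704 at 1.04 ± 0.10. The chitin-binding protein gene Gasp (0.92 ± 0.17), the cuticle protein genes Cpr49Ae (0.90 ± 0.20) and Cpr92F (0.87 ± 0.20) and the adult cuticle protein gene Acp1 (0.84 ± 0.17) rose. Jon25Biii, a digestive serine protease gene, rose by 0.91 ± 0.10, and Lsp2, which encodes a storage protein of the fat body, by 0.85 ± 0.17. CG34291 (0.96 ± 0.15), CG40198 (0.83 ± 0.14) and CG34327 (0.82 ± 0.19) completed the 12 highest. Adjusted p-values of these 24 genes ran from 1.52e-14 to 0.0167, and the rule for naming required the same sign in all 5 pairs. The insulin target gene tobi (-0.31), the gluconeogenic gene Pepck1 (0.41, adjusted p = 0.0509), the lipase gene bmm (-0.13), the insulin receptor gene InR (-0.11) and Yp1 (-0.03) did not pass.

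**Figure D2:**
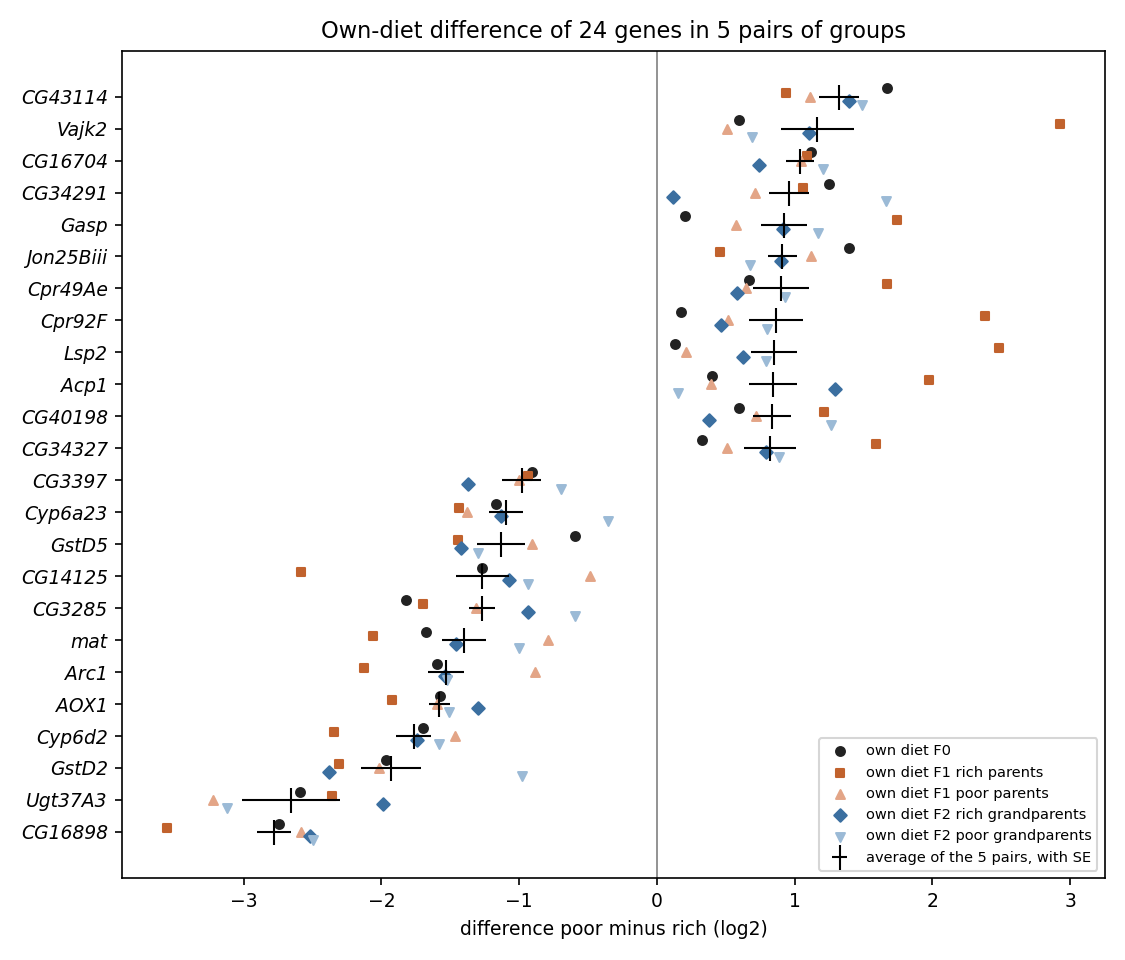
Poor minus rich difference (log2) of the 24 genes named for own diet on average, with 1 symbol per pair of groups and a cross for the average of the 5 pairs with its standard error. The genes were chosen among calls with the same sign in every pair, and run from CG16898 at -2.78 to CG43114 at 1.32 on average.

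Of 15309 probe sets, limma called 281 for own diet on average, 131 higher and 150 lower after poor food, and 14 of them differed at least 2-fold. Quantile normalization split the calls into 166 higher and 152 lower, and centring into 168 and 150. At an unadjusted p under 0.05 there were 1562, against 765 by chance. Of the 281 calls, 234 had the same sign in all 5 pairs, which calling on the average itself favours, and 89 were called in at least 1 pair alone. AOX1, CG16898 and Cyp6d2 were called in every pair. CG16898 averaged 5.09 to 5.85 in the 5 rich-raised groups and 1.98 to 3.33 in the 5 poor-raised groups. The average stood at 254 calls without the 2 arrays with ovary transcripts and at 170 (149 of them among the 281) without the R-R and R-P pair, where Vajk2, Cpr92F, Lsp2, Acp1 and CG34327 no longer passed. Without replicates 1 and 3 of R-R alone it stood at 192, and Vajk2 (0.78 ± 0.23), Cpr49Ae (0.57 ± 0.16), Acp1 (0.65 ± 0.17) and CG34327 (0.63 ± 0.19) no longer passed. Of 2 called genes with several probe sets, both had probe sets that disagreed.

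**Figure D3:**
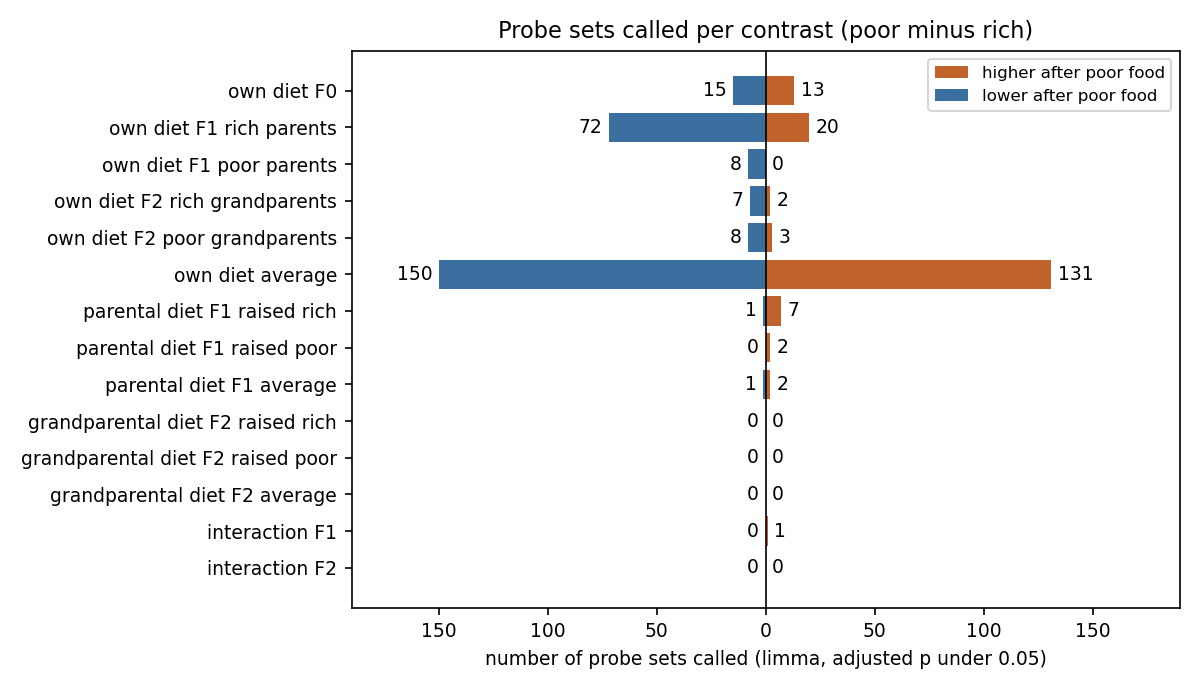
Number of probe sets called by limma at an adjusted p under 0.05 in each of the 14 contrasts, with bars to the right for higher and to the left for lower after poor food (for interactions, a more positive or more negative own-diet effect under poor ancestry). Own diet on average gave 281 calls, the 5 single pairs 8 to 92, and the ancestral contrasts 0 to 8.

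**Figure D4:**
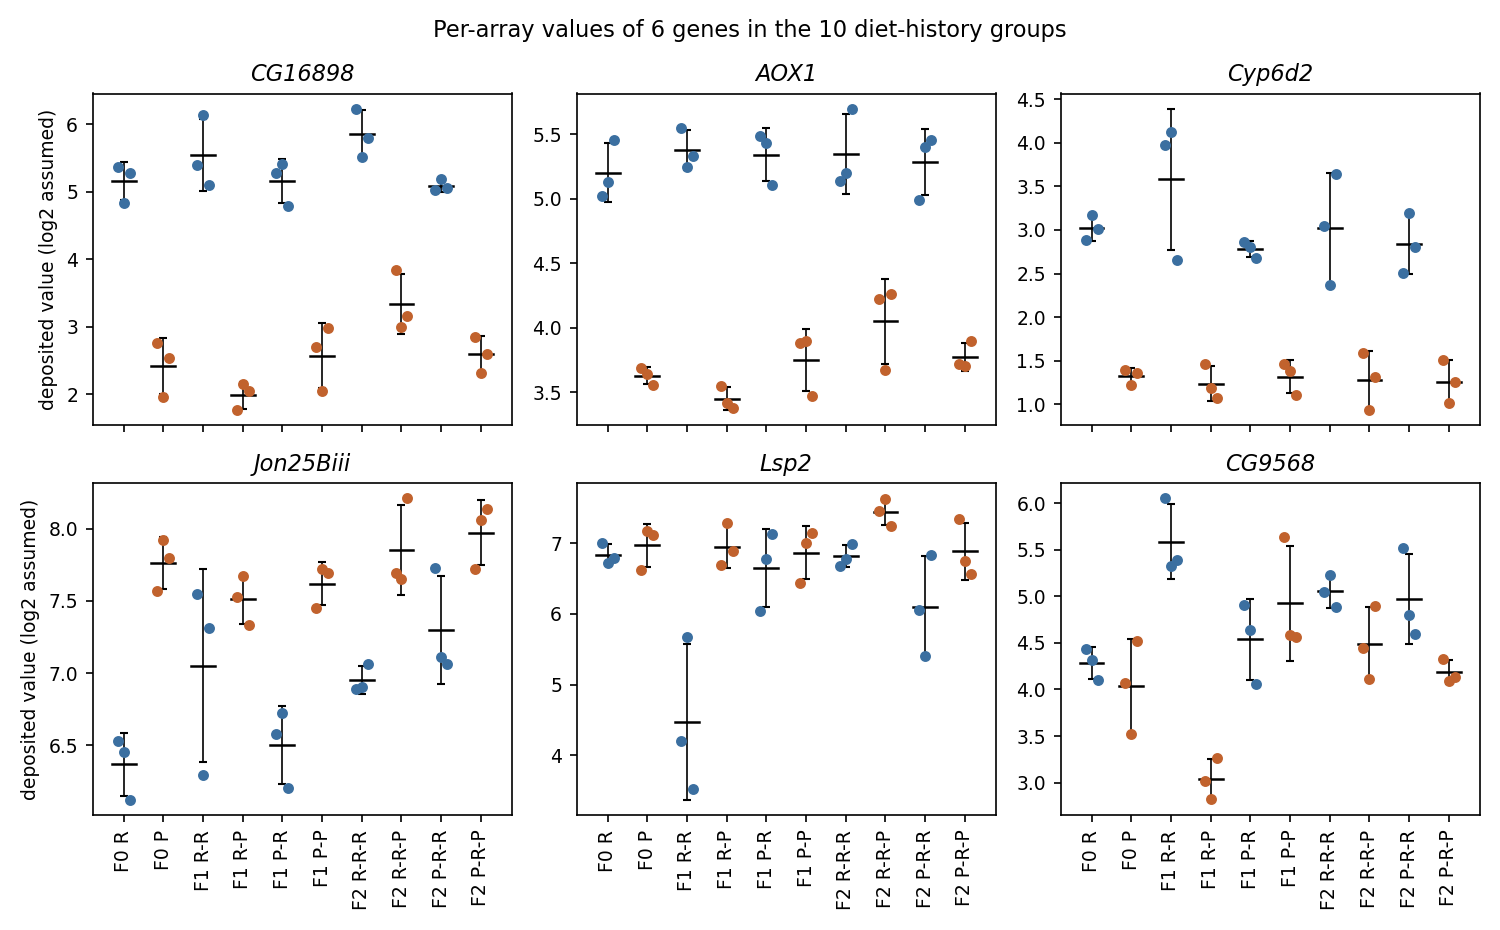
Deposited value (log2 assumed) of 6 genes on each array (points, 3 per group), with group means (horizontal lines) and SD (vertical lines), orange for poor-raised and blue for rich-raised flies. CG16898 lies at 1.98 to 3.33 on average in poor-raised and at 5.09 to 5.85 in rich-raised groups, and Lsp2 averages 4.47 in R-R against 6.10 to 7.44 in the other groups.

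Detoxification genes made the largest group of lower calls: of 147 measured, 16 fell and 1 rose, and adjusted over the list alone 23 fell and 4 rose. Besides the genes named, GstE7 (-0.94 ± 0.15), GstE1 (-0.62 ± 0.09), Cyp6g1 (-0.57 ± 0.13), Cyp9b2 (-0.51 ± 0.08) and GstD1 (-0.39 ± 0.05) fell, and the metallothionein gene MtnA rose by 0.33 ± 0.06. The detoxification list as a whole lay lower (mean -0.11, camera adjusted p = 0.00167), a call that did not hold with an estimated correlation (adjusted p = 0.173). Of 22 Malpighian tubule genes, salt (-0.72 ± 0.12), the potassium channel gene Irk3 (-0.43 ± 0.09) and the diuretic hormone receptor gene Dh31-R (-0.28 ± 0.07) fell. Adjusted over the list alone 5 fell and 1 rose (mean -0.09, camera adjusted p = 0.00249, and adjusted p = 0.0642 with an estimated correlation). Of 37 ribosome biogenesis genes 0 passed in limma, also adjusted over the list alone, with a mean of -0.09 (camera adjusted p = 2.98e-04). With an estimated correlation its adjusted p was 0.276, and 0.00562 without the 2 arrays with ovary transcripts.

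Of 42 carbohydrate metabolism genes 5 rose and 0 fell in limma, namely the sorbitol dehydrogenase gene Sodh1 (0.65 ± 0.09), the hexokinase genes Hex-C (0.56 ± 0.09) and Hex-A (0.28 ± 0.06), the gluconeogenic gene fbp (0.47 ± 0.12) and the glycolytic gene Pglym78 (0.28 ± 0.06). Adjusted over the list alone 16 rose and 0 fell, with a list mean of 0.13 (camera adjusted p = 5.76e-11, and adjusted p = 0.0647 with an estimated correlation). Of 82 oxidative phosphorylation genes 6 rose and 0 fell, among them the respiratory chain genes UQCR-14 (0.40 ± 0.07), UQCR-11 (0.31 ± 0.07), ND-B22 (0.30 ± 0.07) and ND-B17 (0.25 ± 0.06). Adjusted over the list alone 18 rose and 0 fell, with a mean of 0.11 (camera adjusted p = 1.37e-13, and adjusted p = 0.173 with an estimated correlation), and 3 rose without the 2 arrays with ovary transcripts and 1 without replicates 1 and 3 of R-R. Of 27 muscle genes the troponin gene TpnC4 rose by 0.58 ± 0.11, and 13 rose adjusted over the list alone (mean 0.18, camera adjusted p = 5.65e-10, and adjusted p = 0.173 with an estimated correlation). Of 17 fat body and larval storage genes Lsp2 rose, and 2 rose adjusted over the list alone (mean 0.16, camera adjusted p = 0.00992, and adjusted p = 0.173 with an estimated correlation). The list mean was 0.69 in R-P against R-R and 0.02 over the 4 other pairs, where the camera call ended (adjusted p = 0.116). Lsp2 differed by 2.48 in R-P against R-R and by 0.13 to 0.79 in the others. The list, which includes the yolk gene Yp3, shares 3 genes with the female and ovary list, so ovary transcripts widen the gap between these means. Yp1 differed by 1.87 in R-P against R-R and by -2.05 in P-R-P against P-R-R. Neither mean is given here without the 2 arrays with ovary transcripts.

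Of 118 cuticle genes 10 rose and 0 fell in limma, and adjusted over the list alone 14 rose and 1 fell. Examples beside Cpr49Ae and Cpr92F are Cpr97Eb (0.79 ± 0.20), Cpr97Ea (0.75 ± 0.15), Cpr100A (0.75 ± 0.17) and Acp65Aa (0.55 ± 0.09). The list mean was 0.07 (camera adjusted p = 0.0266, and adjusted p = 0.231 with an estimated correlation). Its camera call ended without the 2 arrays with ovary transcripts (adjusted p = 0.119), where 7 rose. It ended too over the 4 pairs other than R-P against R-R (mean 0.05, adjusted p = 0.262), where 2 of the 118 genes rose, and Cpr92F differed by 2.38 in that pair and by 0.17 to 0.80 in the others. The list lay at 0.04 (adjusted p = 0.482) without replicates 1 and 3 of R-R, where 3 rose and 1 fell, and the 7 other list calls on average were made there too. Quantile normalization ended the cuticle call too, as did leaving out the arrays numbered 1. The same step with the arrays numbered 2 ended the calls of the detoxification and Malpighian tubule lists, and that of the fat body list ended without those numbered 1 or 2.

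The other 17 lists were not called for own diet on average, with camera adjusted p from 0.201 to 0.950, although single members passed. Of 72 accessory gland genes 8 rose and 1 fell, and adjusted over the list alone 9 rose and 3 fell. They include the seminal peptide gene Dup99B (0.51 ± 0.06), Obp51a (0.51 ± 0.06) and Acp54A1 (0.68 ± 0.11), while the glucose dehydrogenase gene Gld fell by 0.56 ± 0.10. Acp1 and Acp65Aa, which entered this list by the form of their names, encode adult cuticle proteins. Of 66 gut digestion genes 4 rose and 2 fell (adjusted over the list alone 8 and 4), with Jon65Ai at 0.74 ± 0.11, the lipase gene mag at 0.42 ± 0.10, the trypsin gene thetaTry at -0.51 ± 0.13 and Mur29B at -0.42 ± 0.11. Of 16 circadian clock genes 3 fell and 0 rose, also adjusted over the list alone: tim (-0.44 ± 0.10), vri (-0.40 ± 0.10) and Pdp1 (-0.27 ± 0.05). Of 29 eye and neuron genes the phototransduction genes trpl (-0.51 ± 0.11), Arr1 (-0.38 ± 0.07) and Arr2 (-0.37 ± 0.08) fell, and 5 fell adjusted over the list alone. Over the 4 pairs other than R-P against R-R, and so with fewer arrays, 0 clock genes passed in limma and 1 eye and neuron gene fell. There 3 gut digestion genes rose and 0 fell, and 5 accessory gland genes rose and 1 fell.

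Among 48 immune effector genes, the antimicrobial peptide genes Listericin (-0.71 ± 0.16) and Drs (-0.67 ± 0.11) and the immune regulator gene pirk (-0.66 ± 0.13) fell and IM33 rose by 0.34 ± 0.08. Adjusted over the list alone 4 rose and 5 fell. Among 45 lipid metabolism genes the lipid carrier gene Apoltp fell by 0.86 ± 0.08 and Dgat2 by 0.27 ± 0.07, and the lipid droplet gene Lsd-1 rose by 0.33 ± 0.09 (adjusted over the list alone 3 rose and 5 fell). Of 41 amino acid genes the tyrosine hydroxylase gene ple rose by 0.73 ± 0.14 and AsnS, for asparagine synthetase, fell by 0.52 ± 0.13 (adjusted over the list alone 1 and 2). Of 34 insulin and TOR genes the TOR inhibitor gene Sesn rose by 0.31 ± 0.08 and ImpL2, whose product binds insulin-like peptides, fell by 0.31 ± 0.08 (adjusted over the list alone 1 and 3). Of 249 odorant-binding and chemosensory genes Obp51a and Obp56e rose and ppk18 fell, also adjusted over the list alone. Over the 4 pairs other than R-P against R-R, with fewer arrays, 0 insulin and TOR genes rose and 1 fell in limma. There 1 immune effector gene rose and 2 fell, and 0 lipid genes rose and 1 fell. For amino acid and for chemosensory genes 1 rose and 0 fell. Limma called 0 genes of the Turandot and heat shock (20 measured), cytosolic ribosomal protein (36), proteasome (28), testis (55), Y-linked (9), female and ovary (35), chromatin and piRNA (51) and cell cycle (28) lists. Adjusted over the list alone 1 Turandot and heat shock gene fell and 0 genes of the 7 other lists passed. Median, mean and test differed in sign for the gut digestion, lipid metabolism, accessory gland, female and ovary, and eye and neuron lists.

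In F0, where ancestors were not treated, CG16898 (-2.74 ± 0.27, adjusted p = 2.70e-06), CG3285 (-1.82 ± 0.21), Cyp6d2 (-1.70 ± 0.28), mat (-1.68 ± 0.36) and CG11893 (-1.60 ± 0.34) fell. CG43114 (1.67 ± 0.33, adjusted p = 0.0278), Jon25Biii (1.40 ± 0.23), mag (1.27 ± 0.23), CG17633 (1.19 ± 0.20) and Sodh1 (1.12 ± 0.20) rose. Apoltp (-1.01), Dup99B (0.64) and the testis gene tomb (0.80) were called too. Limma called 28 probe sets (13 higher, 15 lower; 957 at an unadjusted p under 0.05). The Malpighian tubule list lay lower (mean -0.22, camera adjusted p = 5.85e-05) and held with an estimated correlation (adjusted p = 0.00439), with 0 of 22 genes called in limma and 4 lower adjusted over the list alone. Camera also placed the carbohydrate (mean 0.15), gut digestion (0.16), immune effector (0.15) and oxidative phosphorylation (0.10) lists higher and the eye and neuron list lower (-0.13), with adjusted p from 0.376 to 0.804 with an estimated correlation.

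The F0 count moved by more than 1.5 times without replicate 2 of R (17 calls), replicate 3 of R (7), replicate 1 of P (17) and replicate 3 of P (12), and each of the 6 arrays ended the call of at least 1 of the 10 genes other than CG16898, CG3285 and Cyp6d2. With only R and P in the model 17 were called, 13 of them among the 28.

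In F1 flies of rich-raised parents, R-P against R-R, CG16898 (-3.56 ± 0.27, adjusted p = 9.38e-09), the mannosidase gene LManVI (-2.92 ± 0.60), CG14125 (-2.58 ± 0.43), CG9568 (-2.55 ± 0.29) and Cyp6d2 (-2.35 ± 0.28) fell. Vajk2 (2.93 ± 0.59), Lsp2 (2.48 ± 0.37, adjusted p = 7.15e-04), Cpr92F (2.38 ± 0.44), Acp1 (1.98 ± 0.39) and Cpr97Eb (1.95 ± 0.45) rose. Limma called 92 probe sets (20 higher, 72 lower; 1367 at an unadjusted p under 0.05). Of 66 gut digestion genes 5 fell and 0 rose, among them the maltase genes Mal-A3 (-1.61 ± 0.29) and Mal-A2 (-1.32 ± 0.31) and thetaTry (-1.45 ± 0.28), and adjusted over the list alone 14 fell (mean -0.33, camera adjusted p = 2.17e-04, and adjusted p = 0.311 with an estimated correlation). Of 147 detoxification genes 6 fell and 0 rose, adjusted over the list alone 23 and 2 (mean -0.21, camera adjusted p = 1.68e-04, and adjusted p = 0.106 with an estimated correlation). Apoltp fell by 1.33 ± 0.19 and pirk by 1.76 ± 0.30, and ple rose by 1.69 ± 0.31. These differences include replicates 1 and 3 of R-R and replicate 2 of R-P, and are not given here without them. Without the 2 arrays with ovary transcripts 1 gut digestion and 3 detoxification genes fell, and without replicates 1 and 3 of R-R 0 and 1 did in limma.

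Camera placed 15 lists apart in this pair, and 0 with an estimated correlation (adjusted p from 0.106 to 0.611). The female and ovary list was the most displaced (mean 0.83, camera adjusted p = 2.90e-11), with 0 of 35 genes called, and lay at 0.03 without the 2 arrays (adjusted p = 0.151). The testis (mean -0.13), Malpighian tubule (-0.13), odorant-binding and chemosensory (0.02), chromatin and piRNA (0.07) and cell cycle (0.19) lists likewise lost their calls without them. The muscle (mean 0.35), fat body (0.69), cuticle (0.14), oxidative phosphorylation (0.10), carbohydrate (0.07), lipid (-0.12) and immune effector (-0.20) lists kept theirs at the preset correlation. Without replicates 1 and 3 of R-R the calls of the muscle (mean 0.11, adjusted p = 0.0520), cuticle (0.00), oxidative phosphorylation (-0.06), carbohydrate (0.05), lipid (-0.01), testis (0.02), Malpighian tubule (-0.04) and chemosensory (0.01) lists ended. The fat body (0.54, adjusted p = 0.0493), immune effector (-0.15, adjusted p = 0.0493), gut digestion (-0.28) and detoxification (-0.22) lists were still called there at the preset correlation, as were the female and ovary, chromatin and piRNA and cell cycle lists.

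Without the 2 arrays the pair had 41 calls (3 higher, 38 lower; 38 of the 41 among the 92), and Vajk2 (2.80 ± 0.67), Acp1 (1.86 ± 0.43), Cpr97Eb (1.87 ± 0.50) and LManVI (-2.68 ± 0.67) no longer passed, each within 1 standard error of its difference with them. Counts fell to 32 and 42 without replicates 1 and 3 of R-R and to 33 and 49 without replicates 2 and 3 of R-P, and to 20 with only these groups in the model. CG16898, CG9568, CG14125, Cyp6d2 and Lsp2 passed without each single array, and these 4 arrays and replicate 1 of R-P each ended the call of at least 1 of the other 5 genes. Without both replicates 1 and 3 of R-R the pair had 15 calls, and the difference was 0.51 for Cpr92F, 0.36 for Cpr97Eb, 1.01 for Vajk2, 1.01 for Acp1 and 1.27 for Lsp2, none of them past the threshold. LManVI (-2.83 ± 0.88) and CG14125 (-2.67 ± 0.62) did not pass there either.

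In F1 flies of poor-raised parents, P-P against P-R, CG16898 (-2.59 ± 0.27, adjusted p = 8.28e-06), AOX1 (-1.59 ± 0.17), Cyp6d2 (-1.47 ± 0.28, adjusted p = 0.0432) and CG3285 (-1.31 ± 0.21) fell. Limma called 8 probe sets with 5 distinct profiles (0 higher, 8 lower; 670 at an unadjusted p under 0.05). Quantile normalization split the calls into 2 higher and 9 lower. Camera placed the carbohydrate (mean 0.11) and muscle (0.13) lists higher and the detoxification (-0.11) and cytosolic ribosomal protein (-0.11) lists lower, with adjusted p from 0.856 to 0.970 with an estimated correlation. Array quality weights gave 19 calls, and 2 were left without replicate 2 of P-R, which ended the call of CG3285. Leaving out any of the 6 arrays, or fitting the replicate number as a block, ended that of Cyp6d2, while CG16898 and AOX1 passed without each array.

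In F2 flies of rich-raised grandparents, R-R-P against R-R-R, the pigmentation gene t rose by 1.01 ± 0.17 (adjusted p = 0.0105) and ACC, for the enzyme that opens fatty acid synthesis, by 0.94 ± 0.17 (adjusted p = 0.0196). CG16898 (-2.52 ± 0.27), Cyp6d2 (-1.74 ± 0.28), Arc1 (-1.54 ± 0.29), AOX1 (-1.30 ± 0.17) and Cyp4e3 (-0.99 ± 0.19) fell, with adjusted p from 1.58e-05 to 0.0369. Limma called 9 probe sets (2 higher, 7 lower; 1186 at an unadjusted p under 0.05). Quantile normalization gave 17 calls, split into 6 higher and 11 lower. Camera called 9 lists: carbohydrate (mean 0.19), oxidative phosphorylation (0.15), proteasome (0.19), cytosolic ribosomal protein (0.16), muscle (0.27) and accessory gland (0.11) higher, and detoxification (-0.11), Y-linked (-0.15) and odorant-binding and chemosensory (-0.06) lower. With an estimated correlation 0 held (adjusted p from 0.310 to 0.864), and the accessory gland call ended without the 2 arrays with ovary transcripts. Array quality weights gave 42 calls and a model of only these groups 2, the count was 23 without replicate 1 of R-R-R and 2 without replicate 2 of R-R-P, and each array but replicate 1 of R-R-R ended the call of at least 1 of t, ACC, Cyp6d2, Arc1 and Cyp4e3.

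In F2 flies of poor-raised grandparents, P-R-P against P-R-R, CG34291 (1.66 ± 0.33, adjusted p = 0.0400), CG16704 (1.21 ± 0.23) and MtnA (0.64 ± 0.13) rose. CG16898 (-2.50 ± 0.27, adjusted p = 1.81e-05), CG4757 (-1.90 ± 0.32), Cyp6d2 (-1.58 ± 0.28), Drs (-1.55 ± 0.25) and Arc1 (-1.52 ± 0.29) fell. Limma called 11 probe sets (3 higher, 8 lower; 1351 at an unadjusted p under 0.05). The calls split into 5 higher and 8 lower under quantile normalization and into 6 and 8 under centring. The circadian clock list lay lower (mean -0.23, camera adjusted p = 4.61e-04, and adjusted p = 0.0125 with an estimated correlation), with 0 of 16 genes called in limma and 3 lower adjusted over the list alone. Camera placed 9 further lists apart: carbohydrate (mean 0.13), oxidative phosphorylation (0.16) and muscle (0.10) higher, and female and ovary (-0.81), ribosome biogenesis (-0.27), cell cycle (-0.25), cytosolic ribosomal protein (-0.18), chromatin and piRNA (-0.16) and proteasome (-0.14) lower. For these 9 the adjusted p ran from 0.216 to 0.534 with an estimated correlation, and without the 2 arrays with ovary transcripts camera kept carbohydrate and oxidative phosphorylation.

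Calls stood at 6 without these 2 arrays, at 7 with the replicate number as a block, at 6 with array quality weights and at 2 with only these groups in the model. The differences of Cyp6d2 (-1.40 ± 0.31), Arc1 (-1.33 ± 0.31), CG16704 (1.08 ± 0.25) and MtnA (0.68 ± 0.15) no longer passed without the 2 arrays (adjusted p from 0.117 to 0.199), each within 1 standard error of its value with them. Without single arrays calls numbered 23 (replicate 1 of P-R-R), 5 (replicate 2 of P-R-R), 3 (replicate 1 of P-R-P) and 4 (replicate 3 of P-R-P), and only CG16898 of the 8 genes passed without each of the 6 arrays.

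The 5 pairs share no arrays. Of the 28 probe sets called in F0, 26 had the same sign in R-P against R-R, 27 in P-P against P-R, 27 in R-R-P against R-R-R and 26 in P-R-P against P-R-R. Conversely 85 of the 92 calls of R-P against R-R, 4 of the 8 of P-P against P-R, 9 of the 9 of R-R-P against R-R-R and 11 of the 11 of P-R-P against P-R-R had their sign in F0. The 4 probe sets of P-P against P-R with the other sign, which share all their values, had it in each of the 4 other pairs. The F0 pair and R-P against R-R shared 14 calls, where independent lists would share 0.168, and the 9 other combinations shared 3 to 6. All pairs use the same estimate of each probe set's spread, so their lists are not independent and this baseline may be too low. Across all probe sets the differences of 9 of the 10 combinations of pairs correlated at r from 0.10 to 0.25. For R-P against R-R with P-R-P against P-R-R r was -0.01. These pairs hold the 2 arrays with ovary transcripts, on the poor-raised side in the former and the rich-raised side in the latter. Ovary genes thereby take opposite signs in them, and this r is not given without the 2 arrays. An F test of whether the own-diet effect differed among generations in the line with rich-raised ancestors called 0 of 15309 probe sets in limma (1064 at an unadjusted p under 0.05, smallest adjusted p = 0.121, for CG9568, CG3906 and CG7953). CG14186, CG8509 and Npc2d came next at an adjusted p of 0.177. The F test called 3 with the replicate number as a block, 7 without replicate 1 of R, 8 without replicate 2 of R-R, 1 without replicate 1 of R-R-R and 2 without replicate 2 of P.

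Among flies with only rich food in their history, the F test over R, R-R and R-R-R called 1 probe set, Lsp2 (adjusted p = 0.00795; 1145 at an unadjusted p under 0.05). Lsp2 averaged 6.84 ± 0.15 in R, 4.47 ± 1.10 in R-R and 6.82 ± 0.16 in R-R-R (SD, n = 3 each). The call ended without replicate 1 or replicate 3 of R-R, with trend and robust eBayes and with only these groups in the model. Without both replicates 1 and 3 of R-R there were 0 calls by limma, and the count was 29 without replicate 2 of R-R and 2 without replicate 1 of R-R-R.

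The next question was whether the food of the parents mattered for F1 males raised alike. Among rich-raised F1 flies, P-R against R-R, Lsp2 rose by 2.18 ± 0.37 (adjusted p = 0.00948), the juvenile hormone binding protein gene Jhbp13 by 0.73 ± 0.13 (adjusted p = 0.0122) and CG30197 by 0.70 ± 0.14 (adjusted p = 0.0497). Rab9Db, of the Rab GTPase family, fell by 1.14 ± 0.18 (adjusted p = 0.00948). Limma called 8 probe sets with 5 distinct profiles (7 higher, 1 lower; 840 at an unadjusted p under 0.05). The fat body and larval storage list lay higher (mean 0.50, camera adjusted p = 1.61e-06, and adjusted p = 0.0146 with an estimated correlation), with 1 of 17 genes called and 2 adjusted over the list alone. Camera placed the oxidative phosphorylation (mean 0.17), muscle (0.23), carbohydrate (0.10), cuticle (0.11) and accessory gland (0.07) lists higher and the clock list lower (-0.14), with adjusted p from 0.162 to 0.961 with an estimated correlation. The fat body list lay at 0.35 without replicates 1 and 3 of R-R (camera adjusted p = 0.00439, and adjusted p = 0.411 with an estimated correlation). The calls of the oxidative phosphorylation (0.01), muscle (-0.01), carbohydrate (0.08), cuticle (-0.03) and clock (-0.10) lists ended there, and the accessory gland (0.14) and testis (0.14) lists were called.

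Among poor-raised F1 flies, P-P against R-P, CG9568 rose by 1.89 ± 0.29 (adjusted p = 0.00850) and CG5399 by 1.24 ± 0.22 (adjusted p = 0.0408), the 2 calls made (1007 at an unadjusted p under 0.05). Without the 2 arrays with ovary transcripts 0 probe sets passed in limma, with CG9568 at 1.79 ± 0.32 (adjusted p = 0.132) and CG5399 at 1.14 ± 0.24 (adjusted p = 0.352), each within 1 standard error of its value with them. Camera called 10 lists: gut digestion (mean 0.30), immune effectors (0.18), carbohydrate (0.15), detoxification (0.10) and oxidative phosphorylation (0.09) higher, and female and ovary (-0.81), cell cycle (-0.21), ribosome biogenesis (-0.16), chromatin and piRNA (-0.09) and cytosolic ribosomal protein (-0.07) lower. With an estimated correlation 0 held (adjusted p from 0.280 to 0.673), and without the 2 arrays camera kept gut digestion and immune effectors. Adjusted over the list alone 10 gut digestion genes rose.

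On average over rich-raised and poor-raised F1 flies, Jhbp13 (0.59 ± 0.09, adjusted p = 0.00504) and CG14259 (0.56 ± 0.10, adjusted p = 0.0395) rose and Rab9Db fell by 0.87 ± 0.12 (adjusted p = 0.00334) with poor-raised parents, the 3 calls made (1037 at an unadjusted p under 0.05). Rab9Db averaged 1.61 in R-R, 0.47 in P-R, 1.09 in R-P and 0.50 in P-P. Its means in P-R and P-P lay below the medians of all arrays (0.82 to 0.94), where signal near background limits how a fall is measured. Quantile normalization left 1 call, split into 0 higher and 1 lower, and CG14259 (0.57 ± 0.11) no longer passed without the 2 arrays with ovary transcripts. The fat body and larval storage list lay higher (mean 0.17, camera adjusted p = 2.22e-05, and adjusted p = 0.0401 with an estimated correlation), with 0 of 17 genes called and 5 higher adjusted over the list alone. The clock list lay lower (mean -0.11, camera adjusted p = 0.00563, and adjusted p = 0.0401 with an estimated correlation), with 0 of 16 called. Without the 2 arrays the estimated-correlation adjusted p was 0.0156 for the fat body and 0.0800 for the clock list. These lists lay at 0.10 and -0.09 without replicates 1 and 3 of R-R, called at the preset correlation (adjusted p = 0.00267 and 0.0382) and not with an estimated one (0.245 for each). Camera placed 12 further lists apart with adjusted p from 0.253 to 0.587 with an estimated correlation, among them female and ovary (mean -0.40), whose call ended without the 2 arrays (0.00). The calls of the muscle (mean 0.12), oxidative phosphorylation (0.13), detoxification (0.05) and chromatin and piRNA (-0.07) lists ended without replicates 1 and 3 of R-R (0.00, 0.05, 0.04 and -0.03).

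Among rich-raised F1 flies 0 calls remained without replicate 1 or 3 of R-R or replicate 2 of P-R, and 41 were made without replicate 2 of R-R; among poor-raised F1 flies the count was 5, 0 and 1 without replicates 1, 2 and 3 of R-P and 0 and 1 without replicates 1 and 2 of P-P; on average it was 21 without replicate 2 of R-R. Array quality weights gave 18, 1 and 6 calls in these 3 contrasts and a model of only the groups compared 0, 0 and 0, while Jhbp13 and Rab9Db passed on average without each of the 12 arrays. Without both replicates 1 and 3 of R-R limma called 0 in rich-raised flies and 0 on average, with Lsp2 at 0.97 in rich-raised flies and Jhbp13 at 0.48 and Rab9Db at -0.79 on average. Of the arrays compared, each but replicate 2 of R-R ended the call of at least 1 of Lsp2, Jhbp13, CG30197 and Rab9Db in rich-raised flies, each but replicate 1 of R-P that of CG9568 or CG5399 in poor-raised flies, and each but replicate 2 of R-R and of P-P that of CG14259 on average.

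For the food of the grandparents, with rich-raised parents in every case, limma called 0 of 15309 probe sets among rich-raised F2 flies (P-R-R against R-R-R; 1312 at an unadjusted p under 0.05, smallest adjusted p = 0.0988). It called 0 among poor-raised F2 flies (785, smallest adjusted p = 0.371) and 0 on average (843, smallest adjusted p = 0.161). The smallest p-values on average belonged to CG12374 (0.74 ± 0.15), the serine protease gene Jon65Aiv (0.71 ± 0.15) and CG14301 (0.48 ± 0.10) with positive differences, and to Cyp6g2 (-0.59 ± 0.11), Jhbp12 (-0.81 ± 0.16) and CG17560 (-1.31 ± 0.26) with negative ones (adjusted p from 0.161 to 0.210). Among rich-raised F2 flies they belonged to CG4757 (1.64 ± 0.32), CG12374 (1.09 ± 0.22), Jon65Aiii (0.98 ± 0.20), tobi (-1.62 ± 0.32), Cyp4e3 (-0.92 ± 0.19) and Cyp6g2 (-0.81 ± 0.16), with adjusted p near 0.099. Among poor-raised F2 flies they belonged to Cyp4d21 (0.77 ± 0.15), CG14301 (0.62 ± 0.15), ranshi (0.52 ± 0.12), tbrd-3 (-1.08 ± 0.26), Vha36-2 (-0.94 ± 0.22) and Hph (-0.68 ± 0.14), with adjusted p from 0.371 to 0.469.

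Camera called 11, 5 and 9 lists in these 3 contrasts, and 0 with an estimated correlation. The female and ovary list lay higher with poor-raised grandparents (mean 0.79 in rich-raised flies, 0.41 on average), and its calls ended without the 2 arrays. Among the others on average, gut digestion (mean 0.07) lay higher and carbohydrate metabolism (-0.10), detoxification (-0.08) and oxidative phosphorylation (-0.07) lower, with an adjusted p of 0.652 with an estimated correlation for each, and the calls of the carbohydrate and oxidative phosphorylation lists ended without the 2 arrays. Calls appeared on leaving out replicate 2 of R-R-R (4 in rich-raised flies), replicate 3 of P-R-R (9 in rich-raised flies and 4 on average), replicate 3 of R-R-P (1 in poor-raised flies), replicate 3 of R-R-R (1 on average) and replicate 1 of P-R-P (1 on average).

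The last question was whether ancestral food altered the response to a fly's own food. In F1 the interaction was called for 1 probe set (745 at an unadjusted p under 0.05), CG9568, at 2.94 ± 0.41 (adjusted p = 0.00168). CG9568 averaged 5.59 ± 0.40 in R-R and 3.03 ± 0.22 in R-P, but 4.54 ± 0.43 in P-R and 4.93 ± 0.62 in P-P (SD, n = 3 each). In F2 the interaction was called for 0 probe sets in limma (1169 at an unadjusted p under 0.05), and the smallest adjusted p, 0.299, was shared by Su(Ste):CR42433 (0.82 ± 0.19), CG31673 (0.78 ± 0.18), CG42696 (0.78 ± 0.18), feo (-1.32 ± 0.30), vari (-0.94 ± 0.19) and mirr (-0.88 ± 0.20). Camera called 9 lists in F1 and 12 in F2, and 0 with an estimated correlation. In F1 gut digestion lay higher (mean 0.38) and fat body and larval storage lower (-0.65), the latter call ending without the 2 arrays with ovary transcripts. Without replicates 1 and 3 of R-R the gut digestion (0.33), female and ovary (-0.78) and cytosolic ribosomal protein (-0.16) lists were still called in F1, and the 6 others were not, among them fat body (-0.50), muscle (0.02), oxidative phosphorylation (0.09) and cuticle (0.05). In F2 the cytosolic ribosomal protein (-0.34), proteasome (-0.34) and clock (-0.28) lists lay lower.

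The F1 interaction gave 6 calls with the replicate number as a block, with array quality weights and with quantile normalization (2 higher, 4 lower), 7 with trend and robust eBayes, 2 without the dimmest probe sets and 0 with only these groups in the model. It gave 11, 2 and 5 calls without replicate 2 of R-R, replicate 1 of R-P and replicate 3 of P-R, CG9568 passed without each array but not without both replicates 1 and 3 of R-R (2.68, 0 calls by limma), and the F2 interaction gave 1 without replicate 3 of R-R-P and 2 without replicate 3 of P-R-P.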

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

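Of the tests in this part, those of the ovary and yolk transcripts, of the calls and differences without the 2 arrays or without replicates 1 and 3 of R-R, of R-P at equal numbers of arrays, of the ancestors' diet behind the shifted score, of scores matched on spread, and of the spread of the score were chosen after the result was seen.

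Ovary and yolk transcripts appeared on replicate 2 of R-P and replicate 2 of P-R-R, both from males. Yolk protein genes exceeded the highest of the 28 other arrays by at least 3.35 on the log2 scale, as female tissue or RNA mixed into these samples would bring, and such mixing is a candidate explanation. A whole female sample under a male name is argued against, since the accessory gland list lay only 0.0436 below the lowest of the 28 other arrays. The diet history of the groups is argued against as well, since the ovary list reached at most 0.473 on the 4 other arrays of these groups. How female material would have entered is open, and no test of it was possible here.

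The pair R-P against R-R had the most calls of the 5 own-diet pairs, 92. Ovary transcripts on replicate 2 of R-P are argued against as the whole cause: without the 2 arrays the median difference of the 20 higher calls was 1.30 (1.40 with them), each of the 20 kept at least 0.67 of its difference, and 38 lower calls were made, against 18 at most in the other pairs. Only 3 higher calls were made without the 2 arrays, but 3 were also made without replicate 3 of R-R, which has no ovary signal, so this count decides nothing. R-R stood apart from the other rich-raised groups in calls from the 4 poor-raised groups other than its partner R-P. Without the 2 arrays it had 73.25 such calls on average (4.5 to 35.5 for the others, whose means include R-P with 2 arrays). With all arrays it had 60 (13.75 to 40.75 for the others). R-P itself gave 92 calls against R-R and 85 against R-R-R with all arrays, and 41 and 50 without the 2. These averages were not repeated without replicates 1 and 3 of R-R. The cuticle list of R-R stands apart on replicates 1 and 3 only. Lsp2 was lowest there, but replicate 2 of R-R (5.68) also lay below all arrays of other groups but replicate 2 of P-R-R (5.40, with ovary transcripts). The next lowest read 6.04. Without replicates 1 and 3 of R-R the difference of R-P against R-R fell from 2.38 to 0.51 for Cpr92F and from 2.48 to 1.27 for Lsp2. It kept its size for LManVI (-2.92 and -2.83) and CG14125 (-2.58 and -2.67). For R-P, a first comparison gave the fewest calls of the poor-raised groups (18.5, others 21.25 to 45.5), but with 2 arrays for R-P and with R-R among the references of the others only, and without R-R and at equal numbers of arrays the 18.5, which rests on 50 calls against R-R-R (17, 3 and 4 elsewhere), lay above 6.33 to 16.1, so whether R-P stands apart is open, as are parental diet, age and batch, which were not tested.

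A score averaging the 28 probe sets called in F0, each signed by its F0 difference, lay nearer the poor-raised level in descendants of poor-raised F0 flies, by 0.35 in F1 (exact permutation p = 0.01) and 0.31 in F2 (exact permutation p = 0.01). The F1 shift was 0.53 in rich-raised flies (0.83 without replicates 1 and 3 of R-R) and 0.17 in poor-raised flies. The score also differed between groups with only rich food in their history. It averaged 0.547 ± 0.236 in R, 0.679 ± 0.267 in R-R and 1.066 ± 0.151 in R-R-R (SD, n = 3 each). R-R-R thus lay further from R and from R-R than the average shifts in F1 and F2. Differences of this size therefore arose without poor-raised ancestors, though between generations, while the shifts compare flies of the same generation. Of the 28 probe sets, 21 moved toward the poor-raised level in F1, 19 in F2 and 14 in both. This overlap is no larger than unrelated movement in F1 and F2 would give. Across all probe sets the parental and grandparental differences on average correlated at r = -0.11. Rich-raised and poor-raised flies correlated at r = 0.08 in their parental and -0.06 in their grandparental differences. The diet of the F0 ancestors may be the cause, as a hypothesis only, and a line-wide rearing or hybridization batch, which the labels do not give, stays open too. A choice of genes helped by the F1 and F2 arrays is argued against by a score from the 6 F0 arrays alone (exact permutation p = 0.015 and 0.03), and ovary transcripts by shifts of 0.346 and 0.352 without the 2 arrays. Random scores of 28 probe sets put the shifts at percentiles 100 and 100, and scores matched on spread too at percentiles 100 and 99.99, but the genes of the score vary together (SD within groups 0.177, median of random scores 0.108), so a difference between lines is not excluded.

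Other ways of dividing the arrays of each contrast were counted beside the real one. With 10 splits, too few for a share under 0.05, the real counts of own diet were 28 in F0, 92 in R-P against R-R, 8 in P-P against P-R, 9 in R-R-P against R-R-R and 11 in P-R-P against P-R-R, where 1 split of 10 (the real one) gave as many and the highest of the others 0, 1, 0, 0 and 1. The same holds for parental diet in rich-raised F1 flies (8 calls, 1 split of 10, highest other 0) and poor-raised F1 flies (2 calls, 1 of 10, highest other 0).

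With 100 splits, own diet on average had 281 calls under the real grouping (1 split of 100, highest other 5). This share is the smallest that the splits can give. In other splits diet differences enter the spread within groups, which lowers their counts. The gap between 281 and 5 argues against a chance division of these arrays, while differences between cultures or batches were not tested. For parental diet on average (3 calls, 2 of 100, highest other 9) and the F1 interaction (1 call, 3 of 100, highest other 2) the shares lie under 0.05 taken singly, but other splits called more and 16 results were tested, so chance is not excluded for them here. It cannot be excluded for the flies with only rich food in their history (1 call, 25 of 100, highest other 11). Where limma called 0, every split gives as many by construction and nothing is tested: grandparental diet in rich-raised F2 flies (10 of 10, highest other 4), poor-raised F2 flies (10 of 10, highest other 0) and on average (100 of 100, highest other 4), the F2 interaction (100 of 100, highest other 11) and own diet by generation (100 of 100, highest other 4). Single splits gave 9 calls for parental diet on average (real count 3) and 11 for the rich-only flies (real count 1). Whether a structure of the samples lies behind these highest counts was not tested. A single split also gave 11 calls for the F2 interaction (real count 0). Splits for the interactions and for own diet by generation mixed rich-raised with poor-raised arrays, so own-diet differences enter their counts. These splits therefore decide neither chance nor structure there. The median of the other splits was 0 for each.

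The interaction of own and ancestral diet passed its threshold for 22 results, 1 gene and 21 lists at the preset correlation. CG9568 stood at 2.94 in F1 (limma adjusted p = 0.00168), a single call for which chance is not excluded here. In F1 camera at the preset correlation singled out gut digestion (0.38), immune effectors (0.16), cytosolic ribosomal proteins (-0.13), oxidative phosphorylation (-0.0726), fat body and larval storage (-0.65), female and ovary (-0.82), muscle (-0.22), cuticle (-0.0924) and cell cycle (-0.18). In F2 it singled out gut digestion (0.0933), lipid metabolism (-0.15), detoxification (0.0885), cytosolic ribosomal proteins (-0.34), ribosome biogenesis (-0.23), proteasome (-0.34), Y-linked (0.24), female and ovary (-0.77), odorant-binding and chemosensory (0.0933), cuticle (0.0435), chromatin and piRNA (-0.18) and circadian clock genes (-0.28). With an estimated correlation 0 of these 21 list calls held (camera adjusted p from 0.504 to 0.781 in F1 and 0.0891 to 0.776 in F2). Without the 2 arrays with ovary transcripts, gut digestion, immune effectors, oxidative phosphorylation and muscle kept their calls in F1, and detoxification, cytosolic ribosomal proteins, proteasome, Y-linked, odorant-binding and chemosensory and clock genes in F2. Without replicates 1 and 3 of R-R the F1 calls of immune effectors (0.11), oxidative phosphorylation (0.0881), fat body (-0.50), muscle (0.02), cuticle (0.05) and cell cycle (-0.18) ended, and gut digestion, cytosolic ribosomal proteins and female and ovary kept theirs.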

How the results depend on the processing

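Leaving out the 2 arrays with ovary transcripts, the R-R and R-P pair, or replicates 1 and 3 of R-R was chosen after the data were seen, and the other settings before. Across the settings other than single left-out arrays, the values of named genes were past or short of the threshold as before in 779 cases, no longer past it in 97 and newly past it in 2, and those of lists for own diet on average in 45 cases and no longer past it in 11. Without single arrays these numbers were 1227, 127 and 17 for genes and 19 and 5 for lists. Across all these settings 0 called values of these genes and lists changed direction. Lists of other contrasts are not part of this count, and some changed sign without replicates 1 and 3 of R-R. The oxidative phosphorylation mean went from 0.096 to -0.065 in R-P against R-R and from -0.073 to 0.088 in the F1 interaction. Counts moved by over 1.5 times are given here, and centring moved none. Except where fewer arrays were used, the cause was not tested.

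Replicate numbers are shared by all groups, and the values gave little sign that they pair the samples. Same-numbered arrays deviated together with a mean r of 0.00806 (other numbers -0.00363) over probe sets. Of 45 pairs of groups 1 lay over 0.1, at r = 0.43, and 12 of 30 arrays were closest to their own number. How the samples were collected or processed cannot be read from these values. With the replicate block, P-R-P against P-R-R had 7 calls, the F1 interaction 6 and own diet by generation 3.

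Quantile normalization gave 17 calls in R-R-P against R-R-R, 1 for parental diet on average and 6 for the F1 interaction. Without the dimmest 40% of probe sets the F1 interaction had 2, and with trend and robust eBayes 7, while the contrast of generations in flies with only rich food in their history (rich-only flies) had 0 (limma). Signal near background limits the dimmest probe sets, and leaving them out moved no other count by over 1.5 times. Array quality weights gave 19 in P-P against P-R, 42 in R-R-P against R-R-R, 6 in P-R-P against P-R-R, 18, 1 and 6 for parental diet in rich-raised flies, poor-raised flies and on average, and 6 for the F1 interaction. With only the groups compared, and so fewer arrays, F0 had 17 calls, R-P against R-R 20, and R-R-P against R-R-R and P-R-P against P-R-R 2 each, while parental diet in rich-raised flies, poor-raised flies and on average, the F1 interaction and the rich-only flies had 0 each (limma). Own diet on average uses all 30 arrays and has no separate value there. Without the 2 arrays with ovary transcripts, R-P against R-R had 41, P-R-P against P-R-R 6 and parental diet in poor-raised flies 0 (limma). Without the R-R and R-P pair, own diet on average had 170. Without replicates 1 and 3 of R-R, R-P against R-R had 15, and parental diet in rich-raised flies and on average, the F1 interaction and the rich-only flies 0 each (limma). Lists had 129 calls in all, 5 with an estimated inter-gene correlation, 83 without the 2 arrays (75 of them among the 129) and 109 without replicates 1 and 3 of R-R (105 among the 129).

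Without single arrays, counts ran for own diet from 7 to 25 in F0, 32 to 114 in R-P against R-R, 2 to 10 in P-P against P-R, 2 to 23 in R-R-P against R-R-R, 3 to 23 in P-R-P against P-R-R and 234 to 345 on average. For parental diet they ran from 0 to 41 in rich-raised flies, 0 to 5 in poor-raised flies and 2 to 21 on average, and for grandparental diet from 0 to 9, 0 to 1 and 0 to 4. They ran from 1 to 11 for the F1 interaction, 0 to 2 for the F2 interaction, 0 to 8 for own diet by generation and 0 to 29 for the rich-only flies, and from 80 to 117 list calls without all arrays of a number, 80 without those numbered 2.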
